A study of Homo sapiens with 72 samples.

How the data were processed

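RNA was sequenced in bulk from human endothelial cells exposed to 1 of 8 drugs or to the solvent DMSO for 24 or 72 h. Per the labels, 4 cell lines were used: endothelial cells differentiated from induced pluripotent stem cells, named iPSC-EC1 and iPSC-EC2, and primary endothelial cells of the aorta, named PAE1 and PAE2. Each line gave 1 library for each condition and time, 72 libraries in all. RNA was isolated with a miRNeasy Micro kit and libraries were made by Novogene, per the labels' protocols.

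The authors deposited 1 table of whole-number read counts per gene symbol for the 72 libraries, with 56269 genes. Trim Galore, STAR, featureCounts and the genome build hg38 are named in the submitters' processing notes; their roles, versions and settings, the gene annotation and whether strand was used in counting are not given in the sources used here. Reads of antisense genes such as GATA2-AS1 and of near-identical copies, among them SULT1A1, the AKR1C genes and ribosomal protein genes with many pseudogenes, may have been shared or lost in that counting, so their values are uncertain. Positions of named genes were taken by symbol from the GENCODE 29 annotation of hg38. CASC5 and ATP5F1 did not match it by symbol.

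Libraries were grouped by the drug, line and time in their titles. All aspirin libraries titled 72 h carry a time characteristic of 24 hours. Each was compared across genes with the other libraries of its line: 4 of the 4 aspirin libraries titled 72 h correlated more closely with the 72 h libraries, and 3 of the 4 titled 24 h with the 24 h libraries. The exception was PAE2 at 24 h, with a mean correlation of 0.9798 with its 24 h libraries and 0.9843 with its 72 h libraries. The titles were kept. No 2 libraries were alike within sampling noise: the closest pair, PAE1 aspirin and PAE1 lapatinib at 72 h, had a chi-square of 7.99 per degree of freedom over 5000 genes.

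Genes were kept by filterByExpr at its defaults (minimum count 10), which left 19086. Counts were scaled by TMM and fitted with edgeR's quasi-likelihood model (glmQLFit, glmQLFTest; edgeR 4.0.16, R 4.3.3) in 1 fit of all 72 libraries, with the cell line within each time as a block and 48 residual degrees of freedom. The common dispersion was 0.107 and the prior degrees of freedom were 6.5. Each drug was compared with DMSO at its time (4 libraries against 4), carfilzomib with bortezomib, and the 8 drug effects at 72 h with those at 24 h in 1 joint test. A second fit held the 8 DMSO libraries, with 15060 genes, to compare 72 with 24 h. For comparisons of the cell types, the 24 and 72 h counts of a line were added, so that a line counted once: 4 DMSO sums (17067 genes) and 36 sums of all conditions (21748 genes). In these n was 2 lines of each cell type. P-values were adjusted by Benjamini and Hochberg over the genes tested in a comparison, and called at 0.05. Levels are CPM (edgeR's cpm, scaled by library size and TMM factor) with the SD over lines; log2 values per line used a prior count of 2.

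The block follows the design, since the same 4 lines received every condition, and the numbers 1 to 4 stand for iPSC-EC1, iPSC-EC2, PAE1 and PAE2. It was checked from each library's deviation from its group mean: 288 pairs of libraries of the same line and time correlated across genes at 0.29 to 0.88 (median 0.72), and 972 pairs of other lines at -0.75 to 0.61 (median -0.46). No label says that libraries of a line were separate cultures. Drug p-values measure the spread of changes between lines, pooled over conditions, perhaps partly technical.

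Gene lists, 33 in all, were fixed before the data were examined, as were the comparisons, the alternatives planned and the rule for naming genes. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and adjusted over the lists within a comparison. Camera compares a list with all other genes. Beside it stand the number of members called over all genes and the number called when p-values were adjusted over the list alone. With the correlation between genes estimated for each list, none of the 122 calls passed the threshold, and that p-value is given with each list described. Besides stress, cell cycle, metabolic and endothelial programmes, the lists held markers of other cells the cultures could contain: pluripotent cells, cardiomyocytes, epithelial cells, blood cells and mesenchymal cells.

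Named genes were, for each drug and time, the 6 rising and 6 falling genes with the largest change among called genes with a mean of at least 10 CPM and the same direction in all 4 lines; up to 3 members of each of the 5 lists with the smallest adjusted p; and, whether called or not, genes of the drugs' targets and handling and 8 genes of endothelial function. For the cell types, the times and the pair of proteasome inhibitors, 4 genes in each direction were taken, and for a drug's difference between cell types the 4 with the smallest adjusted p. X-inactivation and Y-linked genes were left out. CYP2B6, a cyclophosphamide target of that rule, was not among the genes tested. Other genes named here were chosen after their values were seen, and are marked so. A few results that these rules select are not reported here.

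On simulated counts with real means and library sizes, the drug test (as doxorubicin at 24 h, 18649 genes) recovered 48% of 100 genes changed by 1 (log2) and 99% of 100 by 2, with 3 false calls among 150. The cell type test (as sunitinib, 19081 genes) recovered 18% and 86%, with 4 false among 108, and the DMSO time test (14971 genes) 52% and 97%, with 3 false among 152. With no change (as aspirin at 24 h) the drug test made 0 calls. Camera called 1 of 1 list moved by 0.5, 0 of 32 others and 0 of 33 unmoved. With correlated genes these rates may not hold.

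Fixed beforehand for comparison were fits with no filter on low counts, the median-of-ratios size factors of DESeq2 in edgeR, the DESeq2 1.42.0 test, the model without the replicate block, a fit of only the 8 libraries compared, the times of a line as separate libraries in the cell type tests, leaving out each line in turn, and, for lists, an estimated correlation and fry on voom values. Added after seeing the data were a fit without 4 libraries in which more than 3500 tested genes had no count (iPSC-EC2 DMSO at 24 h, PAE1 DMSO at 72 h, PAE2 bortezomib at 24 h and PAE2 doxorubicin at 24 h), a comparison of each drug with the mean of the other 7, and an offset for GC content and transcript length with the replicate block. GC content and length could be matched to 16056 of the 19086 genes (84.1%).

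Total counts per library ran from 15587404 to 31490699 at 24 h and from 16269057 to 25844040 at 72 h. At this depth a level of 10 CPM rests on more than 100 counts per library. Counting error was not compared with the spread between lines. Reads without molecular identifiers are not independent molecules, so counting floors cover counting error only. The median log2 change over all genes tested lay within 0.054 of 0 in every drug comparison.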

Results

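Counts per gene were measured by bulk RNA sequencing in 72 libraries of human endothelial cells, the cells that line blood vessels. Endothelial cells derived from induced pluripotent stem cells (lines iPSC-EC1 and iPSC-EC2) and primary aortic endothelial cells (PAE1 and PAE2) were each exposed to DMSO, aspirin (1 uM), bortezomib (0.002 uM), carfilzomib (0.025 uM), chloroquine (1 uM), cyclophosphamide (100 uM), doxorubicin (0.05 uM), lapatinib (1 uM) or sunitinib (0.1 uM) for 24 or 72 h. Every drug and time thus had 4 libraries, 1 per line, beside 4 DMSO libraries of the same lines, with 15587404 to 31490699 counts per library. The series asks which transcriptional changes these drugs cause in endothelium. Unless stated otherwise, changes are log2 values against DMSO with the fit's SE (n = 4 lines) and p-values adjusted over all genes tested.

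Before any drug, the PAE and iPSC-EC lines differed most in genes that 1 of the cell types nearly lacked. The interferon-induced IFI27 had 7664 counts in PAE cells and 3 in iPSC-EC, a ratio of 2520 after scaling (exact Clopper-Pearson 95% counting interval 861 to 12200), and the herpesvirus entry receptor TNFRSF14 was higher in PAE by 6.53 ± 0.53 on the log2 scale (adjusted p = 0.028). Of the genes without a count in PAE cells, the matrix gene FBLN1 was at least 3940-fold higher in iPSC-EC (133 CPM, adjusted p = 0.031), the fetal gene DLK1 at least 1780-fold (60.2 CPM), the neural transcription factor SOX11 at least 1070-fold (36.2 CPM) and GPC4 at least 768-fold (26 CPM, adjusted p = 0.028). Each fold used a floor of 3 counts over the group, or 0.0338 CPM. The pluripotency genes DPPA4 and LIN28B, the mesenchymal genes SNAI2 and THY1 and the lymphatic endothelial marker LYVE1 were lower in PAE cells, while VWF, NOS3 and PTGS1 were higher. In all, 135 of 17067 genes were called with n = 2 lines of each type, 33 higher and 102 lower in PAE. This count was 1521 without iPSC-EC1, 1900 without iPSC-EC2 and 0 without either PAE line, and 2014 in DESeq2. It was 0 without the iPSC-EC2 library at 24 h (3694 tested genes at 0) and the PAE1 library at 72 h (5086), which left 1 time in each of these lines; the adjusted p was then 0.065 for IFI27, 0.06 for TNFRSF14, SOX11 and GPC4, 0.085 for FBLN1 and 0.072 for DLK1, each in the same direction. Adjusted over the list alone, 16 of 24 NRF2 targets were higher in PAE, 10 of 25 mesenchymal, 10 of 19 TGF-beta and 12 cholesterol genes were lower, and epithelial markers were split, with 3 higher and 4 lower. Without the 2 libraries these were 11, 10, 7 and 17, and 3 higher and 2 lower. Interferon genes higher in PAE in the list alone numbered 4 of 28 (median 1.1), and 15 of 29 without the 2 libraries (median 1.8).

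In DMSO alone, genes of cell division had a lower median at 72 than at 24 h. Over all 15060 genes tested in edgeR none was called, with 671 at an unadjusted p under 0.05, 81 called in DESeq2 and 139 without the filter on low counts. Adjusted over the list alone, 32 of 32 genes of mitosis and G2/M were lower at 72 h (median change -1.9), with line medians of -0.24 in iPSC-EC1, -2.86 in iPSC-EC2, -2.15 in PAE1 and -2 in PAE2. Of the 8 DMSO libraries compared, iPSC-EC2 at 24 h had 3694 tested genes at 0 and PAE1 at 72 h 5086. Without them, with 2 lines left at both times, the mitosis list was at -1.1 with 0 called in the list alone, and over all genes 0 were called. With all libraries, 4 genes of the ATF4 amino acid and stress response were higher (list median 0.94; 1 and 0.41 without them).

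**Figure D1:**
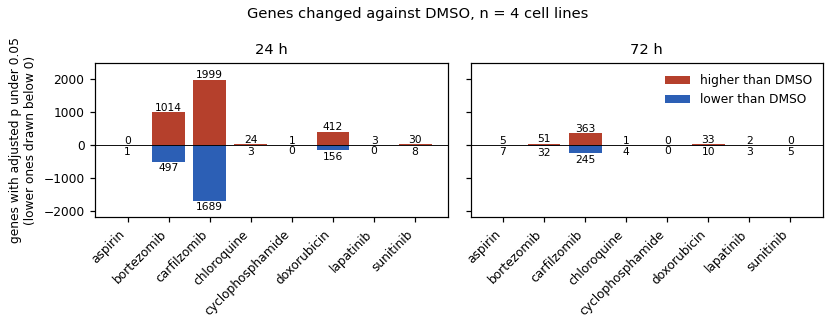
Genes with an adjusted p under 0.05 for each drug against DMSO at 24 h and 72 h, n = 4 lines; bars above 0 count genes higher than DMSO and bars below 0 genes lower. Carfilzomib, bortezomib and doxorubicin had the largest counts at both times, with 3688, 1511 and 568 genes at 24 h.

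Across the 8 drugs the changes shared a component, and every drug at a time was set against the same 4 DMSO libraries. The changes of pairs of drugs correlated across genes at a mean r of 0.73 at both times, where simulation with no change and the same shared libraries gave 0.50 at 24 h and 0.51 at 72 h; genes are not independent replicates. The mean of the 8 drugs differed from DMSO in 1283 genes at 24 h, among them the stress regulator NUPR1 (2.94 ± 0.59, adjusted p = 0.0031), the TGF-beta target SKIL (-1.76 ± 0.35, adjusted p = 0.0027) and ANGPTL4 (-1.59 ± 0.29, adjusted p = 0.0015), all chosen after their values were seen. Without the 4 libraries with many genes at 0 this count was 505. At 72 h it differed in 405 genes, 819 without the 4 libraries and 640 with the GC and length offset (376 among the same matched genes without it), among them the membrane peptidase MME (2.09 ± 0.33, adjusted p = 9.5e-05), the collagen receptor MRC2 (-1.26 ± 0.16, adjusted p = 2.4e-06) and CYR61 (-1.34 ± 0.20, adjusted p = 6.0e-05). No label names a batch, so at 24 h a difference in handling of the DMSO libraries and an effect common to the drugs cannot be told apart. Changes of different drugs in different lines, which share no library, correlated across genes at a mean of 0.26 at 24 h and -0.049 at 72 h (0.0031 and 0.0057 simulated). Chance values of single DMSO libraries stay open too, at both times, since the simulation drew each gene independently. Of 161 named called genes set against the mean of the other 7 drugs, 89 lost the call and 15 more also changed direction. Among 178 named called genes, 26 lost the call without iPSC-EC1, 111 without iPSC-EC2, 93 without PAE1 and 114 without PAE2. With no replicate block 152 of 170 lost it, and the DESeq2 test kept all 178.

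Carfilzomib, an irreversible inhibitor of the proteasome's chymotrypsin-like site, raised genes of protein clearance and lowered genes of cell division at 24 h. The catalytic subunit PSMB5 (chr14:23016543-23035230, hg38), the site the drug binds, rose by 1.52 ± 0.26 (adjusted p = 7.1e-05), from 137 ± 37.5 to 387 ± 49.3 CPM (SD), and was higher in 4 of 4 lines. The haem oxygenase gene HMOX1 rose by 4.45 ± 0.70 (adjusted p = 2.9e-05) in 4 of 4 lines, and the co-chaperone BAG3 by 1.89 ± 0.30 (adjusted p = 2.9e-05). The secreted antioxidant enzyme GPX3 rose by 4.60 ± 0.61 (adjusted p = 2.6e-06), from 23.2 ± 12.2 to 399 ± 130 CPM, and kept its call under every alternative run. Among the largest rises were those of genes at a low level in DMSO: B4GALNT1 (chr12:57623410-57633355) by 6.69 ± 1.06 (adjusted p = 3.0e-05), from 0.651 to 44.9 CPM, KIF1A by 6.02 ± 0.93 (adjusted p = 2.2e-05) and MYH14 by 5.62 ± 0.80 (adjusted p = 1.2e-05), each in 4 of 4 lines. The mitotic genes TOP2A (-2.91 ± 0.75, adjusted p = 0.0049), CENPF (-2.81 ± 0.64, adjusted p = 0.0018) and MKI67 (-2.66 ± 0.72, adjusted p = 0.0075) fell in 4 of 4 lines. Of 19086 genes, 1999 rose and 1689 fell, and 2779 of them moved the same way in all 4 lines. The 3688 calls became 521 without iPSC-EC2, 584 with no replicate block and 7 with the 8 libraries alone. TOP2A was not called without iPSC-EC2 (-2.43, adjusted p = 0.09), and HMOX1 not with no replicate block (3.70, adjusted p = 0.052).

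Of 34 proteasome subunit genes 31 rose with carfilzomib at 24 h, also when adjusted over the list alone, with a median of 1.3 (camera adjusted p = 6.0e-23, and 0.36 with an estimated correlation). Of 21 cytosolic heat shock chaperones 18 rose, 19 adjusted over the list alone (median 1.2, adjusted p = 5.6e-11, and 0.36 with an estimated correlation), led by DNAJB1, which was higher in 2 lines only, at -0.03 to 3.35. The chaperone line medians were 1.94 in iPSC-EC1, 1.55 in iPSC-EC2, 0.18 in PAE1 and -0.03 in PAE2. Of 25 NRF2 antioxidant targets 12 rose, 16 adjusted over the list alone (median 0.96, adjusted p = 1.0e-06, and 0.36 estimated), and of 24 ATF4 targets 9 rose, 11 in the list alone (median 0.82, adjusted p = 1.6e-05, and 0.38 estimated). In the same order of lines the medians were 1.85, 1.65, 0.54 and 0.18 for NRF2 targets and 1.28, 1.15, 0.30 and 0.32 for ATF4 targets. Of 32 genes of mitosis and G2/M 24 fell, 31 adjusted over the list alone (median -2, adjusted p = 8.0e-16, and 0.36 estimated). Lysosomal genes rose in 15 of 30 and fell in 2 (median 0.48, adjusted p = 1.9e-05, and 0.36 estimated). Of 13 mitochondrially encoded messenger RNAs 5 fell, 8 in the list alone (median -0.51, adjusted p = 3.8e-04, and 0.44 estimated). Among 30 genes of endothelial identity 3 rose and 9 fell (median -0.28, adjusted p = 0.0044, and 0.59 estimated), and this call was lost without iPSC-EC1 and without iPSC-EC2. The adhesion gene CDH5 fell by 0.76 ± 0.25 on the log2 scale (adjusted p = 0.028), a call lost without iPSC-EC1 (adjusted p = 0.12), iPSC-EC2 (0.17) or PAE1 (0.077), and against the mean of the other 7 drugs its value was 0.01.

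Bortezomib, a reversible inhibitor of the same site, also raised proteasome and antioxidant genes at 24 h, but unevenly across lines. PSMB2 rose by 1.58 ± 0.26 (adjusted p = 2.5e-04), from 145 to 441 CPM, and PSMB5 by 1.32 ± 0.26 (adjusted p = 0.0014), with line values of -0.04 to 1.98 and a rise in 3 of 4 lines. Both calls were lost without PAE2 (adjusted p = 0.068 and 0.11), and PSMB5 also without iPSC-EC2 (0.058). HMOX1 rose by 3.20 ± 0.67 (adjusted p = 0.0031), at 0.27 to 5.52 in the lines, a call lost without iPSC-EC2 (adjusted p = 0.13) or PAE2 (0.077). B4GALNT1 rose by 6.49 ± 1.05 (adjusted p = 2.5e-04), KIF1A by 5.11 ± 0.93 (adjusted p = 6.3e-04) and PALM3 by 6.68 ± 1.20 (adjusted p = 5.7e-04), each in 4 of 4 lines. The vasoconstrictor gene EDN1 fell by 1.86 ± 0.44 on the log2 scale (adjusted p = 0.007), from 298 ± 164 to 82.1 ± 63.8 CPM, and CDH5 by 1.24 ± 0.25 (adjusted p = 0.0023), from 1880 to 747 CPM, both in 4 of 4 lines. EDN1 lost the call without iPSC-EC2 (adjusted p = 0.091) or PAE2 (0.10), and CDH5 without PAE2 (0.091). The nitric oxide synthase NOS3 rose by 1.23 ± 0.35 (adjusted p = 0.024). In all 1014 genes rose and 497 fell, 945 of them the same way in all 4 lines. The 1511 calls became 2787, 92, 516 and 27 without iPSC-EC1, iPSC-EC2, PAE1 and PAE2 in turn. They became 97 with no replicate block, 0 with the 8 libraries alone and 240 against the mean of the other 7 drugs. Without the 4 libraries with many genes at 0 they became 91. PAE2 bortezomib (3916 at 0) is 1 of the 4, which left only iPSC-EC1 and PAE1 with drug and DMSO. Of the 1511 calls 67.1% rose, and 55.9% of the calls made with an offset for GC content and length, which covers the 16056 matched genes only.

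Of 34 proteasome genes 29 rose with bortezomib at 24 h, 32 adjusted over the list alone (median 1.1, adjusted p = 3.9e-23, and 0.40 with an estimated correlation). The list's median was -0.04 in iPSC-EC1, 1.43 in iPSC-EC2, 1.08 in PAE1 and 1.86 in PAE2. In the PAE2 library, with 3916 tested genes at 0, ribosomal protein genes were at 1.66 and respiratory chain genes at 1.24; without the 4 libraries with many genes at 0, proteasome subunits in bortezomib at 24 h kept the call (adjusted p = 4.6e-26). Of 25 NRF2 targets 13 rose, 15 in the list alone (median 0.77, adjusted p = 2.9e-07, and 0.40 estimated), and of 30 lysosomal genes 13 rose, among them CTSD (2.23 ± 0.41) and GLA (1.86 ± 0.34), with 17 higher and 1 lower in the list alone (median 0.52, adjusted p = 1.9e-06, and 0.40 estimated). Of 19 TGF-beta targets 7 fell, 9 in the list alone, led by SKIL (-2.19 ± 0.56, adjusted p = 0.012; list median -0.61, adjusted p = 7.4e-04, and 0.41 estimated). Genes of mitosis and G2/M had a median of -1.1 with 0 called over all genes or adjusted over the list alone (camera adjusted p = 3.6e-07, and 0.74 estimated). Their line medians ran from -3.21 in iPSC-EC2 to 0.32 in iPSC-EC1. Of 21 heat shock chaperones 3 rose (median 0.35, adjusted p = 0.0048, and 0.74 estimated). The mitosis call was lost without iPSC-EC2 (adjusted p = 0.16), as was that of the heat shock list.

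**Figure D2:**
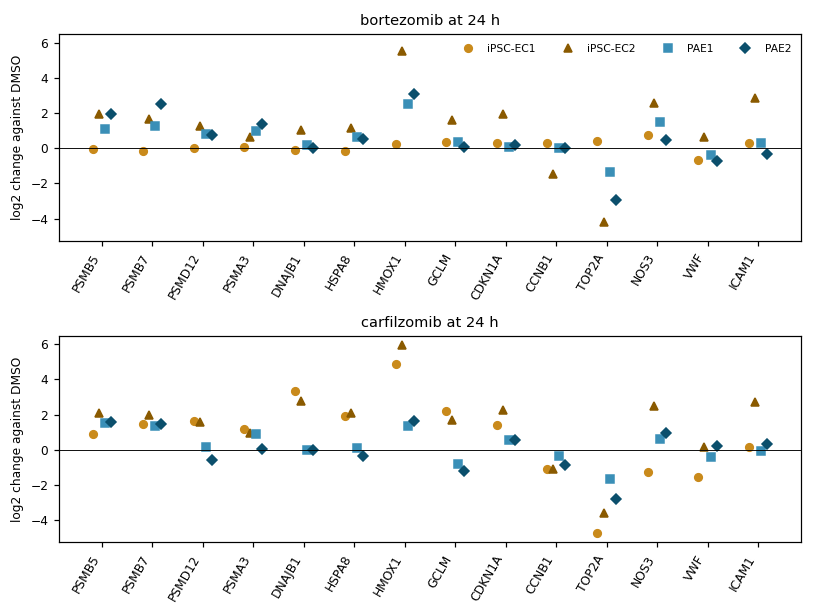
Log2 change against DMSO at 24 h of 14 genes in each cell line, for bortezomib (upper panel) and carfilzomib (lower panel); each point is 1 library against the DMSO library of its line. With bortezomib iPSC-EC1 lies near 0 for PSMB5 (-0.04), and with carfilzomib DNAJB1 is high in the iPSC-EC lines alone.

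Set directly against bortezomib at 24 h, carfilzomib gave higher DNAJB1, DUSP1 and PMAIP1, while no proteasome subunit gene was called. The doses were 0.025 and 0.002 uM, so drug and dose cannot be told apart. DNAJB1 was higher with carfilzomib by 1.76 (95% interval 1.12 to 2.41, adjusted p = 0.02), the phosphatase DUSP1 by 1.36 ± 0.29 and the apoptosis gene PMAIP1 by 1.13 ± 0.24 (adjusted p = 0.043 for both). The 4 other called genes were lower. The count of 7 genes became 54 in DESeq2, 3 without iPSC-EC2, 28 without PAE1, 2 without PAE2, 34 without the 4 libraries with many genes at 0, 16 with the GC and length offset, 0 without iPSC-EC1 and 0 with no replicate block. The difference in PSMB5 was 0.20 (95% interval -0.31 to 0.71), in PSMB2 -0.08 (-0.59 to 0.43), in HMOX1 1.25 (-0.03 to 2.52), in EDN1 1.15 (0.28 to 2.02, adjusted p = 0.40) and in BAG3 1.25 (0.67 to 1.84, adjusted p = 0.079). At 72 h edgeR called 0 genes, with 1033 at an unadjusted p under 0.05, 3 in DESeq2 and 5 without iPSC-EC2. There PDGFRB differed by -2.20 (-3.45 to -0.96, adjusted p = 0.52), PLK1 by -2.26 (-3.51 to -1.02), OASL by 4.28 (1.98 to 6.58) and PSMB5 by 0.19 (-0.32 to 0.70).

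Doxorubicin, which poisons topoisomerase II and breaks DNA, raised p53 targets at 24 h. The cell cycle inhibitor CDKN1A rose by 1.23 ± 0.26 (adjusted p = 0.01), from 456 ± 190 to 1010 ± 182 CPM, at 0.47 to 2.16 in the 4 lines, the damage-recognition gene DDB2 by 1.10 ± 0.22 (adjusted p = 0.0067) and FDXR by 1.40 ± 0.34 (adjusted p = 0.021). CDKN1A lost the call without iPSC-EC2 (0.95, adjusted p = 0.13), PAE1 (1.31, adjusted p = 0.055) or PAE2 (1.22, adjusted p = 0.21). The lipid carrier FABP4 (3.10 ± 0.79, adjusted p = 0.026) and the water channel AQP1 (3.03 ± 0.80, adjusted p = 0.03) rose, and SKIL (-2.16 ± 0.56, adjusted p = 0.028), CTGF (-1.52 ± 0.42, adjusted p = 0.039) and the tubulin TUBE1 (-1.36 ± 0.24, adjusted p = 0.0027) fell, each in 4 of 4 lines. AQP1 was at 5.82 in iPSC-EC2 and 2.48 to 2.75 in the other lines, and SKIL at -5.40 in PAE2 and -2.15 to -1.57 in the others. Against the mean of the other 7 drugs none of these 5 was called (FABP4 0.22, AQP1 0.23, SKIL -0.45, CTGF -0.30, TUBE1 -0.57), nor was CDKN1A (0.81, adjusted p = 0.052), DDB2 (0.62) or FDXR (0.91). The drug's targets were at -2 ± 0.74 for TOP2A (adjusted p = 0.10) and -0.80 ± 0.26 for TOP2B (adjusted p = 0.066). In all 412 genes rose and 156 fell. Without the 4 libraries with many genes at 0 the 568 calls became 19. PAE2 doxorubicin (4058 at 0) is 1 of the 4, which left only iPSC-EC1 and PAE1 with drug and DMSO. The 568 became 1895, 12, 18 and 0 without iPSC-EC1, iPSC-EC2, PAE1 and PAE2 in turn. They became 0 with no replicate block, 1543 in DESeq2 and 8 against the mean of the other 7 drugs. Of those called 72.5% rose, and 54.3% with the GC and length offset. Of 31 p53 targets 8 rose, 15 adjusted over the list alone (median 0.6, adjusted p = 7.7e-07, and 0.47 with an estimated correlation), with line medians of 0.13 in iPSC-EC1, 1.06 in iPSC-EC2, 0.59 in PAE1 and 0.03 in PAE2. Genes of mitosis and G2/M had a median of -1.3, with 0 called over all genes and 19 lower in the list alone (adjusted p = 2.2e-10, and 0.85 estimated), and a line median of 0.50 in iPSC-EC1. Lysosomal genes rose in 4 of 30, 14 in the list alone with 1 lower (median 0.39, adjusted p = 8.7e-06, and 0.48 estimated).

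Chloroquine, a weak base that collects in lysosomes, raised FABP4, NUPR1 and CEBPD at 24 h, with none of 30 lysosomal genes called, also when adjusted over the list alone (median 0.22, adjusted p = 0.0072, and 0.82 with an estimated correlation). Set against the mean of the other 7 drugs, the direction of the lysosome list reversed (adjusted p = 0.11). FABP4 rose by 4.32 ± 0.82 (adjusted p = 0.017), NUPR1 by 2.95 ± 0.66 (adjusted p = 0.045) and CEBPD by 1.61 ± 0.32 (adjusted p = 0.024), and ANGPTL4 (-2.46 ± 0.46, adjusted p = 0.017) and ANKRD1 (-1.54 ± 0.31, adjusted p = 0.025) fell, each in 4 of 4 lines. Set against the other 7 drugs NUPR1 was at 0.01, and FABP4 was not called (adjusted p = 1). FABP4 lost the call without PAE1 (adjusted p = 0.06) or PAE2 (0.23), and NUPR1 without iPSC-EC2 (0.11), PAE1 (0.32) or PAE2 (0.24). The lysosomal membrane gene LAMP1 was at 0.12 (adjusted p = 0.66), and the sterol regulator SREBF2 at 0.65 ± 0.16 (adjusted p = 0.069). Of 27 genes 24 rose (88.9%), 22 of 28 with DESeq2 size factors (78.6%) and 55.7% of those called with the GC and length offset. The 27 calls became 92 without iPSC-EC1, 7 without iPSC-EC2 or PAE1, 0 without PAE2, 0 with no replicate block, 195 in DESeq2 and 0 against the other drugs. Of 24 cholesterol genes 3 rose adjusted over the list alone and 0 over all genes (median 0.59, adjusted p = 1.6e-06, and 0.82 with an estimated correlation). Of 19 TGF-beta targets 7 fell in the list alone (median -0.58, adjusted p = 5.2e-05, and 0.56 estimated).

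Sunitinib, an inhibitor of receptor tyrosine kinases of vessel growth, raised 30 genes at 24 h, among them NUPR1 (3.65 ± 0.67, adjusted p = 0.0098), FABP4 (3.65 ± 0.80, adjusted p = 0.033), the fatty acid receptor CD36 (2.83 ± 0.64) and CEBPD (1.67 ± 0.32, adjusted p = 0.014), each higher in 4 of 4 lines except NUPR1, at 0 in iPSC-EC2. NUPR1 lost the call without PAE1 (adjusted p = 0.17) or PAE2 (0.13). NPTXR fell by 2.27 ± 0.48 on the log2 scale (adjusted p = 0.028). Its kinase targets were not called: KDR was at -0.31 (adjusted p = 0.57), FLT1 at -0.87 (adjusted p = 0.16) and KIT at -0.43. In all 30 genes rose and 8 fell, and 51.2% of those called rose with the GC and length offset. The 38 calls became 129 without iPSC-EC1, 12 without iPSC-EC2, 4 without PAE1, 3 without PAE2, 0 with no replicate block, 230 in DESeq2 and 0 against the other drugs. Of 24 ATF4 targets 10 rose adjusted over the list alone and 0 over all genes (median 0.66, adjusted p = 1.3e-06, and 0.95 with an estimated correlation).

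With lapatinib, an inhibitor of the receptors EGFR and ERBB2, genes of cholesterol synthesis and uptake shifted upward at 24 h as a group. Of 24 such genes 16 rose adjusted over the list alone and 0 over all genes (median 0.72, adjusted p = 3.7e-10, and 0.53 with an estimated correlation), with line medians of 0.06 in iPSC-EC1, 1.54 in iPSC-EC2, 0.67 in PAE1 and 0.57 in PAE2. Over all genes FASN was at 1.02 ± 0.26 and SREBF2 at 0.64 ± 0.16 (adjusted p = 0.097 for both). The 3 genes called all rose: AIF1L by 2.02 ± 0.38 (adjusted p = 0.016), BACE2 by 0.81 ± 0.15 (0.014) and, named after its value was seen, PTP4A3 by 2.19 ± 0.44 (0.041). AIF1L lost the call without iPSC-EC2 (adjusted p = 0.12), PAE1 (0.056) or PAE2 (0.10). EGFR was at -0.52 (adjusted p = 0.63) and ERBB2 at 0.13 (0.84). The count was 96 without iPSC-EC1, 0 without iPSC-EC2, 6 without PAE1, 0 without PAE2, 0 with no replicate block and 142 in DESeq2. The share that rose was 75% with DESeq2 size factors and 57.7% with the GC and length offset. TGF-beta targets were lower, 6 in the list alone against 1 higher (median -0.42, adjusted p = 4.9e-04, and 0.53 estimated).

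Cyclophosphamide, an alkylating agent that liver enzymes must activate, changed 1 gene at 24 h. The antisense transcript GATA2-AS1 rose by 1.31 ± 0.24 (adjusted p = 0.019), from 7.21 to 16.2 CPM, in 4 of 4 lines. It was not called without iPSC-EC1 (adjusted p = 0.062), iPSC-EC2 (0.12) or PAE2 (0.14). The detoxifying ALDH1A1 was at 0.53 ± 0.71 (adjusted p = 0.77), and CYR61 at -1.19 (adjusted p = 0.094). The count was 63 without iPSC-EC1, 6 without iPSC-EC2, 4 without PAE1, 0 without PAE2, 0 with no replicate block and 120 in DESeq2, and with the GC and length offset 55.6% of the calls rose. Of TGF-beta targets 4 were lower and 1 higher adjusted over the list alone (median -0.6, adjusted p = 1.9e-04, and 0.66 with an estimated correlation). At 72 h edgeR called 0 genes, with 1290 at an unadjusted p under 0.05, 18 in DESeq2, 3 without iPSC-EC1 and 2 without PAE1.

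Aspirin, an inhibitor of the cyclooxygenases, changed 1 gene at 24 h: the semaphorin SEMA4F, named after its value was seen, fell by 1.20 ± 0.22 on the log2 scale (adjusted p = 0.023), though not in all 4 lines. PTGS1 was at -0.22 ± 0.40 (adjusted p = 0.87) and PTGS2 at -0.11 ± 0.45 (adjusted p = 0.95). The adhesion gene VCAM1 was at 2.56 ± 0.68 (adjusted p = 0.21). The count was 47 without iPSC-EC1, 0 without iPSC-EC2, 3 without PAE1, 0 without PAE2, 0 with no replicate block and 42 in DESeq2, and with the GC and length offset 38.1% of the calls rose. Cytosolic ribosomal protein genes, with no member called, had a median of 0.38 (camera adjusted p = 5.9e-05, and 0.98 with an estimated correlation). That list was also called upward at 24 h in the 6 other drugs bortezomib, carfilzomib, chloroquine, cyclophosphamide, doxorubicin and sunitinib, with an adjusted p of 0.62 to 0.99 at an estimated correlation. Set against the mean of the other 7 drugs, the list's direction reversed in aspirin (adjusted p = 0.15), chloroquine (3.3e-04) and cyclophosphamide (4.7e-06). Carfilzomib lost the call.

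**Figure D3:**
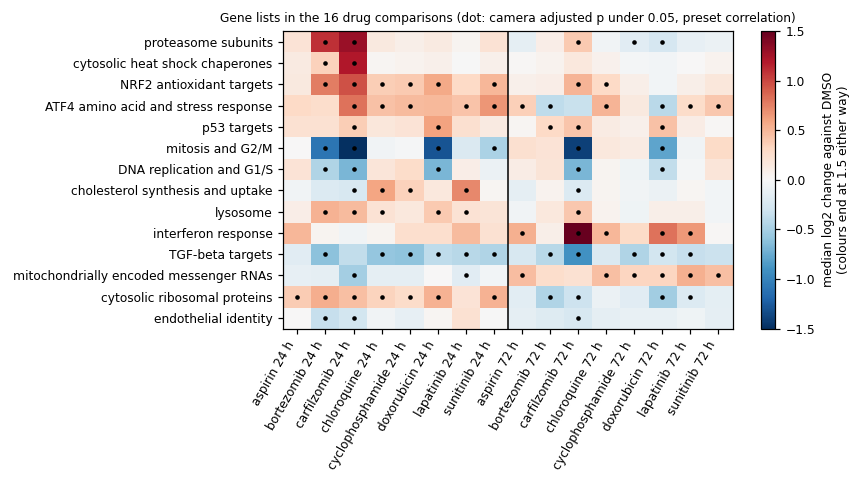
Median log2 change against DMSO of the genes of 14 lists in the 16 drug comparisons, with a dot where camera at the preset correlation gave an adjusted p under 0.05; colours end at 1.5 either way. Proteasome genes were highest with bortezomib (median 1.1) and carfilzomib (1.3) at 24 h, and no dot is left with an estimated correlation.

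At 72 h carfilzomib lowered CYR61, BMP4, CTGF and PDGFRB and raised MMP1. The matricellular gene CYR61 fell by 2.36 ± 0.31 on the log2 scale (adjusted p = 5.5e-06), from 893 to 189 CPM, at -3.05 to -1.32 in the lines, and kept its call without each line in turn. BMP4 (-2.63 ± 0.43, adjusted p = 2.2e-04), CTGF (-2.55 ± 0.44, adjusted p = 4.4e-04), the pericyte receptor PDGFRB (-3.38 ± 0.62, adjusted p = 8.1e-04), BGN (-3.09 ± 0.60, adjusted p = 0.0018) and TAGLN (-2.48 ± 0.61, adjusted p = 0.014) fell, PDGFRB with no change in PAE2 and the others in 4 of 4 lines. Against the mean of the other 7 drugs CYR61 was at -1.15, BMP4 at -1.79, CTGF at -1.51, PDGFRB at -3 and MMP1 at 2.23, all called, while the mean of the 8 drugs was at -1.34 for CYR61, -1.2 for CTGF and -1.06 for BMP4. The collagenase MMP1 rose by 3.11 ± 0.54 (adjusted p = 4.4e-04), from 392 to 2580 CPM, and the transporter SLCO2B1 by 5.6 ± 0.97 (adjusted p = 4.8e-04). EDN1 fell by 1.79 ± 0.43 (adjusted p = 0.012) and CDH5 by 0.99 ± 0.25 on the log2 scale (adjusted p = 0.017). EDN1 lost the call without iPSC-EC1 (adjusted p = 0.088), and CDH5 without iPSC-EC1 (0.067), iPSC-EC2 (0.10) or PAE2 (0.075); against the other 7 drugs CDH5 was at -0.22 (adjusted p = 0.58). PSMB5 was at 0.30 (adjusted p = 0.62), and no proteasome gene was called over all genes, 6 of 34 adjusted over the list alone (median 0.39, adjusted p = 6.1e-05, and 0.52 with an estimated correlation). The line medians were 1.33 in iPSC-EC1, 0.06 in iPSC-EC2, -1.05 in PAE1 and 0.86 in PAE2. In PAE1 the list lay between -1.05 and -0.64 with each of the 8 drugs, all set against its DMSO library with 5086 tested genes at 0, and ribosomal protein genes were at -1.75 with carfilzomib. The proteasome direction reversed without iPSC-EC1 (adjusted p = 0.64), and the call was lost without PAE2 (0.075). In all 363 genes rose and 245 fell, 426 the same way in all 4 lines. The 608 calls became 208 without iPSC-EC1, 264 without iPSC-EC2, 927 without PAE1, 2 with no replicate block, 1671 without the 4 libraries with many genes at 0, and 0 with the 8 libraries alone.

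Of 21 endoplasmic reticulum genes 3 fell with carfilzomib at 72 h, PDIA4 (-0.95 ± 0.21, adjusted p = 0.005), HYOU1 (-1.12 ± 0.27, adjusted p = 0.012) and SYVN1, with 11 lower adjusted over the list alone (median -0.49, adjusted p = 5.0e-08, and 0.13 with an estimated correlation). PDIA4 was not called without iPSC-EC1 (adjusted p = 0.073). Of 19 TGF-beta targets 5 fell, 8 lower and 2 higher in the list alone (median -0.91, adjusted p = 1.2e-06, and 0.13 estimated), and of 27 mesenchymal genes 6 fell, 13 lower and 1 higher in the list alone (median -0.87, adjusted p = 7.9e-05, and 0.32 estimated). The mesenchymal line medians were -1.58 in iPSC-EC1, 0.26 in iPSC-EC2, -0.43 in PAE1 and 0 in PAE2. That list's call was lost without iPSC-EC1 (adjusted p = 0.10). Of 31 p53 targets 6 rose, 9 in the list alone, among them FAS (1.15 ± 0.26, adjusted p = 0.0078; list median 0.42, adjusted p = 5.5e-07, and 0.32 estimated), whose call was lost without iPSC-EC2 (adjusted p = 0.098) or PAE1 (0.054). Of 32 genes of mitosis and G2/M 1 fell, 14 in the list alone (median -1.4, adjusted p = 9.7e-14, and 0.39 estimated). Interferon genes rose in 5 of 29, 14 in the list alone (median 1.7, adjusted p = 5.0e-08, and 0.47 estimated), with line medians of -0.10 in iPSC-EC1, 5.83 in iPSC-EC2, 0.36 in PAE1 and -0.48 in PAE2. The list's direction reversed without iPSC-EC2 (adjusted p = 0.35). OASL rose by 5.61 ± 1.24 (adjusted p = 0.0061), and was not called without iPSC-EC1 (4.79, adjusted p = 0.072) or iPSC-EC2 (adjusted p = 0.13).

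Bortezomib at 72 h raised MME, LYVE1, IGFBP3 and ECM1 and lowered CYR61 and CREB5. MME rose by 2.59 ± 0.39 (adjusted p = 2.6e-04), the lymphatic receptor LYVE1 by 2.93 ± 0.68 (adjusted p = 0.031), IGFBP3 by 2.02 ± 0.46 (adjusted p = 0.028) and ECM1 by 1.51 ± 0.27 (adjusted p = 0.0038), though in iPSC-EC1 LYVE1 was at 0.02, ECM1 at 0.13 and MME at 0.53. CYR61 fell by 1.62 ± 0.31 (adjusted p = 0.008) and the transcription factor CREB5 by 2.13 ± 0.45 on the log2 scale (adjusted p = 0.014). MME and CYR61 lost the call without iPSC-EC2 (adjusted p = 0.47 and 0.58), and set against the other 7 drugs they were at 0.55 and -0.34, LYVE1 at 0.85, IGFBP3 at 0.40, ECM1 at 0.77 and CREB5 at -0.69, none called. The mean of the 8 drugs was at 2.13 for LYVE1 and 2.09 for MME. PSMB5 was at 0.11 (adjusted p = 0.94). In all 51 genes rose and 32 fell, so 61.4% rose, and 50% with DESeq2 size factors. The 83 calls became 196 without iPSC-EC1, 0 without iPSC-EC2, 15 without PAE1, 18 without PAE2, 286 without the 4 libraries with many genes at 0, 167 with the GC and length offset, 0 with no replicate block, 297 in DESeq2 and 4 against the other drugs. Of 19 TGF-beta targets 1 fell, 6 in the list alone (median -0.42, adjusted p = 4.5e-05, and 0.39 with an estimated correlation). Ribosomal protein genes had a median of -0.45 with none called (adjusted p = 2.9e-08, and 1 estimated), with line medians of 0.16 in iPSC-EC1, -0.40 in iPSC-EC2, -1.15 in PAE1 and 0.15 in PAE2. The list's call was lost without PAE1 (adjusted p = 0.59). Without the 4 libraries with many genes at 0, PAE1 DMSO among them, the direction reversed (0.57).

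Doxorubicin raised p53 targets at 72 h as well. Of 31 targets 2 rose, SPATA18 (1.28 ± 0.27, adjusted p = 0.024) and CMBL (0.84, adjusted p = 0.039), and 13 adjusted over the list alone (median 0.44, adjusted p = 5.8e-10, and 0.28 with an estimated correlation), with line medians of 0.12 in iPSC-EC1, 0.82 in iPSC-EC2, 0.50 in PAE1 and 0.66 in PAE2. The secreted OIT3 (2.86 ± 0.60, adjusted p = 0.02) and MME (2.36 ± 0.39, adjusted p = 0.0021) rose, and MRC2 (-1.24, adjusted p = 0.019) and CYTH2 (-0.94, adjusted p = 0.02) fell. Against the mean of the other 7 drugs none of these 6 genes was called, with MRC2 at 0.02, CYTH2 at -0.11, MME at 0.29, OIT3 at 0.78, SPATA18 at 0.66 and CMBL at 0.32. MME lost the call without iPSC-EC2 (adjusted p = 0.12) or PAE1 (0.24), as did MRC2 (0.48 and 0.081). TOP2A was at -0.97 (adjusted p = 0.63) and TOP2B at 0.02. In all 33 genes rose and 10 fell, so 76.7% rose, and 64.5% with the GC and length offset. The 43 calls became 183 without iPSC-EC1, 1 without iPSC-EC2, 2 without PAE1, 8 without PAE2, 98 without the 4 libraries with many genes at 0, 0 with no replicate block, 259 in DESeq2 and 2 against the other drugs. Ribosomal protein genes had a median of -0.52 (adjusted p = 1.6e-11, and 0.70 estimated), with no member called. Their line medians were 0.13 in iPSC-EC1, -0.45 in iPSC-EC2, -1.46 in PAE1 and 0.23 in PAE2. The list's call was lost without PAE1 (adjusted p = 0.69) and without the 4 libraries (0.68). With each of the 8 drugs at 72 h this list had a median of -0.98 or lower in PAE1, whose DMSO library is 1 of the 4. Of 13 venous genes 1 rose, 4 in the list alone (median 0.56, adjusted p = 0.0025, and 0.40 estimated).

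Aspirin, chloroquine, lapatinib and sunitinib at 72 h each lowered MRC2, CLSTN1 and the RNA export gene NXF1, set against the same 4 DMSO libraries. These 3 genes were called lower in all 7 drugs other than cyclophosphamide, and DGCR2 in 6 of them, all but lapatinib. MME was called higher in 6, all but sunitinib. In aspirin MME rose by 1.87 ± 0.38 (adjusted p = 0.025), from 23 to 48.2 CPM, MRC2 fell by 1.23 ± 0.24 (adjusted p = 0.025) and the pacemaker channel HCN2 by 1.40 ± 0.29 on the log2 scale (adjusted p = 0.026). In chloroquine MME rose by 1.93 ± 0.38 (adjusted p = 0.029), and in lapatinib MME rose by 1.98 ± 0.38 and OIT3 by 3 ± 0.60 (adjusted p = 0.025 for both), with OIT3 at 0 in PAE1. In sunitinib MRC2 fell by 1.21 ± 0.24 (adjusted p = 0.028), and BCL6B, named after its value was seen, by 1.29 ± 0.24 (adjusted p = 0.026). Set against the mean of the other 7 drugs MRC2 was at 0.01 to 0.06 in these 4 drugs, and MME at -0.25 in aspirin, -0.18 in chloroquine and -0.12 in lapatinib. Without iPSC-EC2 MRC2 lost the call in each of the 4, at adjusted p = 0.67 in aspirin, 0.74 in chloroquine, 0.71 in lapatinib and 0.63 in sunitinib. Aspirin called 12 genes, 5 higher (41.7%, and 23.5% with the GC and length offset), and the other 3 drugs 5 genes each. In sunitinib none of them rose, and 38.1% of the calls with that offset did. In the order aspirin, chloroquine, lapatinib and sunitinib, the counts of changed genes at 72 h were 71, 109, 72 and 138 without the 4 libraries with many genes at 0 and 101, 57, 75 and 76 in DESeq2. They were 81, 43, 71 and 50 without iPSC-EC1 and 11, 8, 7 and 11 without PAE1, and without iPSC-EC2, without PAE2 or with no replicate block they were 0. Mitochondrially encoded messenger RNAs were shifted upward in all 4, with medians of 0.46, 0.45, 0.53 and 0.45 and 5, 5, 5 and 6 of 13 called adjusted over the list alone, 0 over all genes. The PAE1 medians were 0.66 to 0.80, and the PAE1 DMSO library had the lowest mitochondrial share at 72 h (3.3%) and 5086 tested genes at 0. The list's 4 calls held without the 4 libraries with many genes at 0. Its camera adjusted p ran from 9.7e-08 in sunitinib to 1.2e-06 in aspirin, and from 0.38 to 0.41 with an estimated correlation.

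Lists of ERK output, adhesion and NF-kB, apoptosis, arterial, nitric oxide, tip cell, pluripotency, cardiomyocyte, epithelial and blood genes were called in 0 of the 16 drug comparisons, in each case at the preset correlation. Mesenchymal genes were called lower with carfilzomib at 72 h and higher with sunitinib at 72 h (median 0.27, adjusted p = 0.013, and 0.72 with an estimated correlation). The sunitinib line medians were 0.03 in iPSC-EC1, 1.03 in iPSC-EC2, 0 in PAE1 and 0.36 in PAE2. This call was lost without iPSC-EC2 (adjusted p = 0.65) or PAE2 (0.10). With aspirin, chloroquine, cyclophosphamide, doxorubicin and lapatinib iPSC-EC2 had 1.06 to 1.57, against the same DMSO library.

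The response to carfilzomib differed between 24 and 72 h in 124 genes, 93 of which had the smaller change at 72 h. MME went from -0.38 to 2.97 (by 3.35 ± 0.53, adjusted p = 7.7e-04). AKR1C3 (-2.33 ± 0.47), the chaperones DNAJB1 (-2.11 ± 0.44), FKBP4 (-1.27 ± 0.25) and SERPINH1 (-1.45 ± 0.29) and CYR61 (-2.02 ± 0.43) had lower effects at 72 h (adjusted p = 0.016 to 0.022). There the mean of 8 drugs was 2.09 for MME and -1.34 for CYR61, so part may be shared. The joint edgeR test of the 8 drugs called 0 genes, with 715 at an unadjusted p under 0.05, 21 in DESeq2, 12 without iPSC-EC1 and 1 without iPSC-EC2. The single tests of the other 7 drugs called 0 genes each, with 1032 (aspirin) to 3215 (doxorubicin) at that p. DESeq2 was not run for these. With carfilzomib 158 genes rose and 70 fell at both times, where independent calls would share 38 and 21.7.

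Carfilzomib also changed genes differently in PAE and iPSC-EC lines, with 484 genes called in edgeR and 1330 in DESeq2. The neutrophil chemokine CXCL8 differed in its response by -5.98 ± 0.56 (PAE minus iPSC-EC, adjusted p = 8.1e-06) and kept its call under every alternative run. The chaperones HSP90AA1 (-2.54 ± 0.31, adjusted p = 3.5e-04) and DNAJB1 (-2.34 ± 0.30, adjusted p = 6.7e-04) responded less in PAE, and PPFIBP2 more (2.73 ± 0.36, adjusted p = 7.7e-04). Of 21748 genes tested with n = 2 lines of each type, 189 had a higher and 295 a lower effect in PAE. For 387 of 483 genes the absolute mean change was larger in iPSC-EC. For 384 the mean changes of the cell types had opposite signs, whatever their size, and whether PAE cells changed at all was not tested. Heat shock chaperones responded lower in PAE in 10 of 21, 16 adjusted over the list alone (median -1), interferon genes in 7 of 29, 19 in the list alone (median -2.6), and adhesion and NF-kB genes in 7 of 26 against 1 higher, 14 lower in the list alone. The interferon median against DMSO stood apart in iPSC-EC2 at 72 h alone (5.83), and in iPSC-EC1 it was -0.06 at 24 h and -0.10 at 72 h. Genes of DNA replication and G1/S had higher effects in PAE in 7 of 32, 26 in the list alone (median 1.9), among them MCM2, PCNA and CDC6. The 484 calls became 317 without iPSC-EC1, 806 without iPSC-EC2, 1290 without PAE1, 18 without PAE2, 1 with no replicate block and 978 with the times as separate libraries. Bortezomib had 3 genes, SDC1 (3.20 ± 0.54), LPXN (2.43 ± 0.41) and LINC00702 (5.19 ± 0.89), each with an adjusted p of 0.047; the count was 138 without iPSC-EC1, 0 without iPSC-EC2 or PAE1, 0 with no replicate block and 28 in DESeq2. Aspirin had 1, which was 26 without iPSC-EC1, 0 without iPSC-EC2 or PAE1 and 23 in DESeq2. In edgeR chloroquine, cyclophosphamide, doxorubicin, lapatinib and sunitinib had 0, with 1440, 1114, 1125, 1828 and 1453 at an unadjusted p under 0.05 and 7, 0, 11, 20 and 5 in DESeq2. Without iPSC-EC1 these counts were 8, 7, 44, 68 and 10, without PAE2 they were 1 or 2, and without PAE1 doxorubicin had 67 and lapatinib 1.

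**Figure D4:**
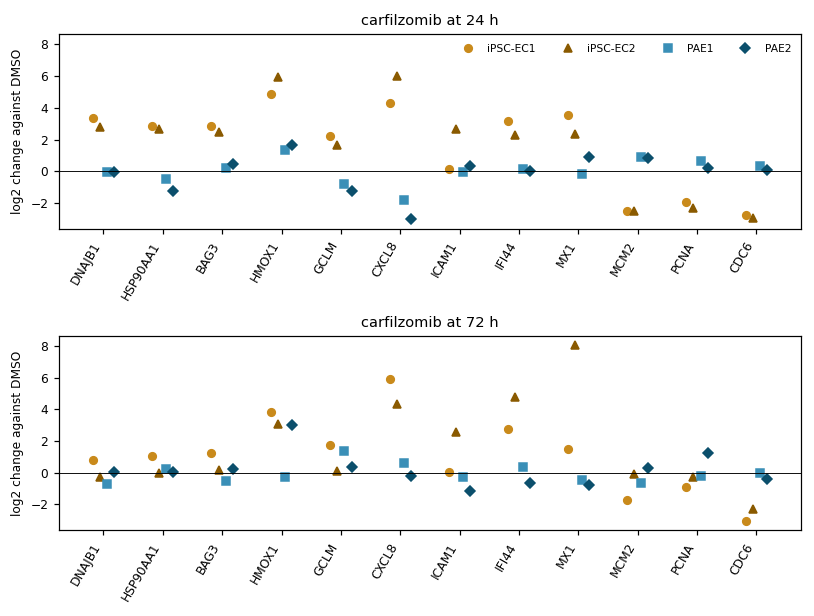
Log2 change against DMSO of 12 genes with carfilzomib in each cell line at 24 h (upper panel) and 72 h (lower panel); each point is 1 library against the DMSO library of its line. CXCL8 lies above 4 in both iPSC-EC lines at both times and under 1 in both PAE lines.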

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

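Of the tests below, those of the correlation between changes of different drugs in different lines and all those on bortezomib in iPSC-EC1 were chosen after the result was seen. A value was taken as far from the others when, among 4 libraries of a group or 4 lines of a comparison, its gap to the nearest value divided by the range exceeded Dixon's 95% critical value; chance alone picks out about 1 in 20 groups. Of library measures 6 values exceeded it, and of the named gene comparisons 39 of 484, 38 of which are given below.

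Among library measures, the total count of PAE2 with aspirin at 24 h stood apart (ratio 0.871), as did the mitochondrial share of iPSC-EC2 with DMSO at 24 h (7.79%, 0.833), iPSC-EC1 with sunitinib at 24 h (7.25%, 0.836) and PAE1 with doxorubicin at 72 h (4.97%, 0.894). The TMM factor of iPSC-EC2 stood apart with chloroquine at 24 h (1.13, 0.888) and cyclophosphamide at 72 h (1.13, 0.845).

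At 24 h these changes stood apart (log2 value, ratio). With carfilzomib these were HMMR in PAE1 (-1.11, 0.847), PSMB7 in iPSC-EC2 (1.95, 0.842), RPL37 in PAE2 (1.23, 0.869) and ICAM1 in iPSC-EC2 (2.7, 0.861). With chloroquine RENBP in iPSC-EC1 (1.3, 0.852) did so, and with cyclophosphamide RPL37 (-0.15, 0.834) and HMOX1 (0.12, 0.853) in iPSC-EC1 and ICAM1 in iPSC-EC2 (2.37, 0.961). With doxorubicin they were AQP1 (5.82, 0.919) and ICAM1 (2.7, 0.847) in iPSC-EC2, VWCE (0.17, 0.84) and CENPE (0.74, 0.852) in iPSC-EC1 and SKIL in PAE2 (-5.4, 0.847), and with lapatinib SELE in iPSC-EC1 (0.58, 0.909).

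At 72 h, aspirin had MT-ATP6 (0.19, 0.844) and MT-ND4 (0.01, 0.884) in iPSC-EC1 and VCAM1 (4.48, 0.837) and VWF (2.65, 0.871) in iPSC-EC2. Bortezomib had LYVE1 (0.02, 0.909) and MME (0.53, 0.966) in iPSC-EC1. Carfilzomib had TAGLN in PAE1 (-5.17, 0.952), CDCA8 in iPSC-EC1 (-2.89, 0.875) and TRIAP1 in PAE2 (1.81, 0.859). Chloroquine had OAS1 (4.07, 0.834) and VWF (2.22, 0.901) in iPSC-EC2, and cyclophosphamide PSMC3 (-1.99, 0.844) and ADRM1 (-1.58, 0.845) in PAE1 and VWF in iPSC-EC2 (2.77, 0.953). Doxorubicin had LYVE1 in iPSC-EC1 (0.62, 0.844), CENPE (1.26, 0.867) and TOP2B (1.44, 0.898) in PAE1, and OASL (5.08, 0.919) and OAS2 (7.44, 0.97) in iPSC-EC2. Lapatinib had IFI6 in iPSC-EC2 (6.56, 0.932) and PSPH (0.11, 0.945) and EGFR (2.14, 0.911) in PAE1. Sunitinib had DGCR2 in iPSC-EC1 (-0.24, 0.87) and VWF in iPSC-EC2 (2.85, 0.902). Values of a line at a time share a DMSO library, so repeats (VWF here, ICAM1 at 24 h, both in iPSC-EC2) are no separate evidence.

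Other effects differed between groups in a test of the difference itself. The effect in PAE minus that in iPSC-EC was 3.2 for SDC1, 5.19 for LINC00702 and 2.43 for LPXN with bortezomib. With carfilzomib it was -3.16 for IFI44, -5.98 for CXCL8, -1.97 for BAG3, 2.73 for PPFIBP2, -2.54 for HSP90AA1, -1.77 for ICAM1, -2.34 for DNAJB1 and -3.66 for HMOX1. The carfilzomib effect at 72 h minus that at 24 h was -2.02 for CYR61, 2.11 for DDX58, -1.27 for FKBP4, -2.29 for BMP4 and -2.11 for DNAJB1.

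The first pattern weighed is that the changes of all 8 drugs from DMSO ran together. Chance values of single DMSO libraries stay open. Changes of different drugs in different lines, which share no library, correlated across genes at 0.26 at 24 h and -0.049 at 72 h. The simulation (0.0031 and 0.0057) drew genes independently. The tables also argue against GC content and transcript length at 24 h, since 1500 genes differed between the mean of the drugs and DMSO with the offset and 1189 without. Open at 24 h are DMSO libraries with many genes at 0, since 505 genes were called without the 4 libraries and 1283 with them. Of these, 1 of DMSO and 2 of drugs were at 24 h, so the fall cannot be put down to DMSO alone. Without the 4, PAE1 DMSO among them, the 72 h count was 819, and 405 with them. Open as well is separate handling of the DMSO libraries, since 0 labels name a batch. A response common to the drugs may be a further explanation at 24 h, and cannot be told apart from handling.

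The second pattern is that carfilzomib changed genes more in iPSC-EC than in PAE lines. Lower depth of the PAE libraries is argued against, as their median total was 1.17 times that of iPSC-EC. DMSO libraries with many genes at 0 are argued against for the difference in 431 of 484 genes. Set against 5 other drugs in place of DMSO, these differed in the same direction, among 4903 in all. Which type changed more was not tested there, so this stays open. A cell type difference in the response may explain it, as a hypothesis from 2 lines of each type; donor, source and culture of the lines stay open.

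The third pattern is that bortezomib left the proteasome genes of iPSC-EC1 near their DMSO level at 24 h, with a median of -0.04. An exchange with a library of that line from the 6 drugs other than carfilzomib is argued against, as their highest median was 0.37; one with its carfilzomib library, at 1.31, was not tested and stays open, though at 72 h the line had 1.33 with carfilzomib and 0.17 with bortezomib, and at 24 h a heat shock median of 1.94 with carfilzomib, where iPSC-EC2 had 1.55 with carfilzomib and 0.98 with bortezomib. Argued against, too, is a shallow library, at 1.14 times the median total of the line. Nor were the cells unable to raise these genes, since they were higher by 1.31 in the carfilzomib library. A smaller bortezomib response of iPSC-EC1, or a lower dose reaching it, may explain the value; at 72 h the median was 0.17, which leaves this open.

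Drug and DMSO labels were swapped within lines in every way, which makes 8 splits with the real one, so a share under 0.05 was out of reach. As many genes as in the real split came in 1 of the 8 splits at 24 h for carfilzomib (3688 real, highest other 1461), chloroquine (27 and 8), cyclophosphamide (1 and 0), lapatinib (3 and 0) and sunitinib (38 and 7), and in 2 for aspirin (1 and 1), bortezomib (1511 and 1580) and doxorubicin (568 and 1498). At 72 h it was 1 for aspirin (12 and 4), bortezomib (83 and 15), doxorubicin (43 and 0) and lapatinib (5 and 3), 2 for chloroquine (5 and 7) and sunitinib (5 and 8), 5 for carfilzomib (608 and 3787) and 8 for cyclophosphamide (0 and 34). For carfilzomib against bortezomib it was 4 at 24 h (7 and 123) and 8 at 72 h (0 and 1), and 8 for the joint test of time (0 and 1) and for DMSO at 72 against 24 h (0 and 0). The 3787 genes of another split for carfilzomib at 72 h, the 1498 for doxorubicin at 24 h, the 34 for cyclophosphamide at 72 h and the 123 for carfilzomib against bortezomib at 24 h point to a structure of the samples. For carfilzomib 484 genes differed between the cell types in a separate test, but whether this made the 3787 was not tested.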

How the results depend on the processing

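Chosen after seeing the data were the fit without the 4 libraries with many genes at 0, the comparison with the mean of the other 7 drugs, and the GC and length offset with the replicate block. The DESeq2 test was not run for gene lists, the model without the block not for PAE against iPSC-EC in DMSO, and the comparison with the other drugs not for carfilzomib against bortezomib. Without the 4 libraries the drug effects were not compared between cell types, and the other added choices were run for neither the cell type nor the time tests. DESeq2 size factors kept the side of the threshold for 177 of 178 named called genes, for 119 of 122 list calls and for 29 of 30 counts (within 1.5 times), the exception being 27 genes in doxorubicin at 72 h. All 178 kept it in the DESeq2 test, 156 with no filter on low counts, 148 with the GC and length offset (14 lost it), 121 of 171 without the 4 libraries, 18 of 170 with no replicate block and 11 of 163 with the 2 groups compared alone.

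The counts of genes moved more. With no filter on low counts they were 67 in aspirin, 225 in chloroquine, 149 in cyclophosphamide, 171 in lapatinib and 227 in sunitinib at 24 h. Those at 72 h were 35 in aspirin, 154 in bortezomib, 29 in chloroquine, 4 in cyclophosphamide, 139 in doxorubicin, 22 in lapatinib and 32 in sunitinib. Further counts were 63 in carfilzomib against bortezomib at 24 h, 65 in carfilzomib against bortezomib at 72 h and the joint test of time, 139 in DMSO at 72 against 24 h and 2554 in PAE against iPSC-EC in DMSO. Those between cell types were 83 in aspirin and bortezomib, 1034 in carfilzomib, 58 in chloroquine, 27 in cyclophosphamide, 50 in doxorubicin, 71 in lapatinib and 51 in sunitinib. In the DESeq2 test they were 42 in aspirin, 2526 in bortezomib, 195 in chloroquine, 120 in cyclophosphamide, 1543 in doxorubicin, 142 in lapatinib and 230 in sunitinib at 24 h. At 72 h there were 101 in aspirin, 297 in bortezomib, 1083 in carfilzomib, 57 in chloroquine, 18 in cyclophosphamide, 259 in doxorubicin, 75 in lapatinib and 76 in sunitinib. Beside these the counts were 54 in carfilzomib against bortezomib at 24 h, 3 in carfilzomib against bortezomib at 72 h, 81 in DMSO at 72 against 24 h, 2014 in PAE against iPSC-EC in DMSO and 21 in the joint test of time. Between cell types the counts were 23 in aspirin, 28 in bortezomib, 1330 in carfilzomib, 7 in chloroquine, 11 in doxorubicin, 20 in lapatinib and 5 in sunitinib. With the 2 groups compared alone, and so fewer libraries to estimate the spread, they were 0 in aspirin, bortezomib, doxorubicin, lapatinib and sunitinib, 7 in carfilzomib, 124 in chloroquine and 3 in cyclophosphamide at 24 h. At 72 h the counts were 0 in aspirin, bortezomib, carfilzomib, chloroquine, doxorubicin, lapatinib and sunitinib. Other counts were 0 in carfilzomib against bortezomib at 24 h. Without the 4 libraries they were 91 in bortezomib, 4 in cyclophosphamide, 19 in doxorubicin and 9 in lapatinib at 24 h. Those at 72 h were 71 in aspirin, 286 in bortezomib, 1671 in carfilzomib, 109 in chloroquine, 4 in cyclophosphamide, 98 in doxorubicin, 72 in lapatinib and 138 in sunitinib. Further counts were 34 in carfilzomib against bortezomib at 24 h, 1 in carfilzomib against bortezomib at 72 h and 0 in PAE against iPSC-EC in DMSO. With the GC and length offset and the replicate block, on fewer genes, they were 42 in aspirin, 158 in chloroquine, 108 in cyclophosphamide, 137 in lapatinib and 164 in sunitinib at 24 h. At 72 h there were 167 in bortezomib, 1015 in carfilzomib, 17 in chloroquine, 121 in doxorubicin, 15 in lapatinib and 21 in sunitinib. Beside these the counts were 16 in carfilzomib against bortezomib at 24 h and 1 in carfilzomib against bortezomib at 72 h. Against the mean of the other 7 drugs they were 0 in aspirin, chloroquine and sunitinib, 240 in bortezomib, 3 in cyclophosphamide and 8 in doxorubicin at 24 h. At 72 h the counts were 0 in aspirin, chloroquine, lapatinib and sunitinib, 4 in bortezomib and 2 in doxorubicin. List calls numbered 227. With the times of a line as separate libraries they were 0 in aspirin and 978 in carfilzomib between cell types. In place of 122 list calls there were 0 with an estimated correlation and 51 by fry, which kept 37 of the 122. Apart from fewer genes or libraries, the cause was not tested.

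The block pairs the libraries of a line at a time. With no replicate block the counts were 0 in aspirin, chloroquine, cyclophosphamide, doxorubicin, lapatinib and sunitinib, 97 in bortezomib and 584 in carfilzomib at 24 h. Those at 72 h were 0 in aspirin, bortezomib, chloroquine, doxorubicin, lapatinib and sunitinib and 2 in carfilzomib. Further counts were 0 in carfilzomib against bortezomib at 24 h. Those between cell types were 0 in aspirin and bortezomib and 1 in carfilzomib. Of the list calls 101 of 122 kept their side of the threshold. This alternative's own construction leaves the differences between lines in the error.

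Leaving out each line in turn gave a range for each count, with the remaining line of a cell type assumed to vary like the other groups where 1 was left. At 24 h the counts ran from 0 to 47 in aspirin, 27 to 2787 in bortezomib, 521 to 3270 in carfilzomib, 0 to 92 in chloroquine, 0 to 63 in cyclophosphamide, 0 to 1895 in doxorubicin, 0 to 96 in lapatinib and 3 to 129 in sunitinib. At 72 h the counts ran from 0 to 81 in aspirin, 0 to 196 in bortezomib, 208 to 927 in carfilzomib, 0 to 43 in chloroquine, 0 to 3 in cyclophosphamide, 1 to 183 in doxorubicin, 0 to 71 in lapatinib and 0 to 50 in sunitinib. The others ran from 0 to 28 in carfilzomib against bortezomib at 24 h, 0 to 5 in carfilzomib against bortezomib at 72 h, 0 to 0 in DMSO at 72 against 24 h, 0 to 1900 in PAE against iPSC-EC in DMSO, 0 to 12 in the joint test of time and 105 to 161 in list calls. Between cell types the counts ran from 0 to 26 in aspirin, 0 to 138 in bortezomib, 18 to 1290 in carfilzomib, 0 to 8 in chloroquine, 0 to 7 in cyclophosphamide, 0 to 67 in doxorubicin, 0 to 68 in lapatinib and 0 to 10 in sunitinib. Of the drug comparisons most had more calls without iPSC-EC1 and fewer without iPSC-EC2 or PAE2; the cause was not tested.

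Some results reversed. Against the mean of the other 7 drugs the log2 change changed sign for VCAM1 (-1.8 in carfilzomib at 24 h), CDH5 (0.01 in carfilzomib at 24 h), MINPP1 (0.05 in sunitinib at 24 h), MME (-0.25 in aspirin at 72 h, -0.18 in chloroquine at 72 h, -0.12 in lapatinib at 72 h), MRC2 (0.02 in aspirin at 72 h, 0.01 in chloroquine at 72 h, 0.02 in doxorubicin at 72 h, 0.04 in lapatinib at 72 h, 0.06 in sunitinib at 72 h), CLSTN1 (0.01 in aspirin at 72 h, 0.03 in chloroquine at 72 h, 0.01 in lapatinib at 72 h, 0.01 in sunitinib at 72 h), DGCR2 (0.02 in chloroquine at 72 h), CYR61 (0.11 in doxorubicin at 72 h) and HCN2 (0.06 in doxorubicin at 72 h). Of lists, whose values here are camera adjusted p-values, the same comparison reversed nuclear-encoded respiratory chain (0.13 in aspirin at 24 h, 0.013 in chloroquine at 24 h, 0.0031 in cyclophosphamide at 24 h, 0.31 in sunitinib at 24 h), cytosolic ribosomal proteins (0.15 in aspirin at 24 h, 3.3e-04 in chloroquine at 24 h, 4.7e-06 in cyclophosphamide at 24 h, 0.066 in lapatinib at 72 h), NRF2 antioxidant targets (0.0092 in chloroquine at 24 h, 0.0039 in cyclophosphamide at 24 h, 0.92 in doxorubicin at 24 h, 0.22 in sunitinib at 24 h), ATF4 amino acid and stress response (0.33 in chloroquine at 24 h, 0.39 in cyclophosphamide at 24 h, 0.28 in lapatinib at 24 h), lysosome (0.11 in chloroquine at 24 h, 0.084 in lapatinib at 24 h), TGF-beta targets (0.62 in doxorubicin at 24 h, 0.52 in sunitinib at 24 h, 0.89 in doxorubicin at 72 h, 0.061 in lapatinib at 72 h), mitosis and G2/M (0.22 in sunitinib at 24 h), interferon response (0.66 in aspirin at 72 h), mitochondrially encoded messenger RNAs (0.57 in cyclophosphamide at 72 h, 0.0093 in doxorubicin at 72 h) and ER chaperones of the unfolded protein response (0.92 in doxorubicin at 72 h, 0.17 in lapatinib at 72 h). Leaving out 1 line reversed further list calls, given with the range of the adjusted p over the 4 lines left out in turn. Without iPSC-EC2 these were DNA replication and G1/S in bortezomib at 24 h (3.2e-05 to 0.43), interferon response in carfilzomib at 72 h (2.6e-10 to 0.35), interferon response in doxorubicin at 72 h (3.3e-09 to 0.5). Without iPSC-EC1 these were proteasome subunits in carfilzomib at 72 h (1.4e-12 to 0.64). Without PAE2 these were nuclear-encoded respiratory chain in carfilzomib at 72 h (5.5e-09 to 0.63). Without PAE1 these were cytosolic ribosomal proteins in carfilzomib at 72 h (7.5e-26 to 0.096), proteasome subunits in cyclophosphamide at 72 h (0.0016 to 0.54), nuclear-encoded respiratory chain in doxorubicin at 72 h (7.2e-05 to 0.83), cytosolic ribosomal proteins in lapatinib at 72 h (2.6e-06 to 0.0065). Without the 4 libraries it reversed for cytosolic ribosomal proteins (0.57 in bortezomib at 72 h, 0.47 in carfilzomib at 72 h, 2.1e-05 in lapatinib at 72 h), proteasome subunits (0.51 in cyclophosphamide at 72 h) and nuclear-encoded respiratory chain (0.51 in doxorubicin at 72 h). The cause was not tested.

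Depth limited few of these results, since the genes named for the largest changes had a mean of at least 10 CPM; in the DMSO sums, a gene under 0.0338 CPM in PAE cells could not be told from 0.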

Other observations

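At 72 h the median change of interferon-response genes was highest in iPSC-EC2 with each of the 8 drugs, a difference between lines that was not tested. Over 29 genes the median log2 change against DMSO in that line was 5.83 with carfilzomib, 3.99 with doxorubicin, 3.59 with lapatinib and 2.73 with chloroquine, and between 1.24 (sunitinib) and 1.51 (cyclophosphamide) with the other drugs. In PAE2 it lay between -0.48 (carfilzomib) and 0.87 (aspirin), in PAE1 between 0.15 (bortezomib) and 0.75 (lapatinib), and in iPSC-EC1 between -0.1 (carfilzomib) and 0.5 (chloroquine). At 24 h the iPSC-EC2 values ran from -0.59 (chloroquine) to 1.5 (lapatinib), with 1.38 for aspirin, 0.95 for doxorubicin and 0.01 for carfilzomib. In DMSO the median of 25 of these genes changed by -1.32 from 24 to 72 h in iPSC-EC2 and by 0.1 to 0.43 in the other lines; the 24 h library of iPSC-EC2 had 3694 tested genes at 0, and which of the 2 libraries was off cannot be read from this. Since all 8 values of iPSC-EC2 at 72 h share 1 DMSO library, their common part rests on that library and is no separate evidence from each drug.

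Line by line, each value below is 1 library against the 1 DMSO library of its line, and differences between lines were not tested. The median change of 32 genes of mitosis and G2/M at 24 h was -3.93 with carfilzomib, 0.32 with bortezomib and 0.50 with doxorubicin in iPSC-EC1. In iPSC-EC2 the corresponding values were -3.23, -3.21 and -3.01. PAE1 had -0.84, -0.47 and -1.31, and PAE2 -1.36, -1.29 and -1.94. The other 5 drugs shared part of these offsets, at 0.27 to 0.94 in iPSC-EC1 and -1.24 to -0.83 in iPSC-EC2, and the iPSC-EC2 DMSO library at 24 h had 3694 tested genes at 0. Genes called at both times in the same direction numbered 18 higher and 13 lower for bortezomib, where independent calls would share 2.71 and 0.833, and 7 higher and 1 lower for doxorubicin, where they would share 0.712 and 0.0817.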
